A study of Homo sapiens with 4 samples.

How the data were processed

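The deposited data were gene-level tables from RNA sequencing of 4 cultures, 1 library per culture, made from 201B7, an established human induced pluripotent stem cell (iPSC) line. Per the labels' protocols, the cells were first driven towards endoderm with CHIR99021 and activin A, then treated for 6 days with dorsomorphin, retinoic acid and SB431542, and finally kept for 8 days in the last medium, which was replaced every 4 days. In that last step the cultures received water (control), sodium cromoglicate (SCG, a mast cell stabiliser used in allergy), a set of 4 factors (4F), or both. The 4 factors were 10 µM forskolin, which raises cyclic AMP, 10 µM dexamethasone, a glucocorticoid, 5 µM Alk5 inhibitor II, which blocks TGF-beta receptor signalling, and 10 mM nicotinamide. The dose of SCG is not given in the sources used here.

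Per the labels' protocols, total RNA was isolated with an RNeasy kit, ribosomal RNA was removed with Ribo-Zero Gold, stranded total RNA libraries were made with an Illumina TruSeq kit, and single reads of 101 cycles were taken on a HiSeq2500. Per the submitters' processing notes, the steps used bcl2fastq, CASAVA 1.8.2, Trimmomatic 0.3.3, TopHat2 2.0.14 and Bowtie2 2.2.5, with the human genome build hg19. Per the file headers, the authors then ran rpkmforgenes (version of 19 Oct 2012) with its options for BAM input and read counts on the RefSeq gene table dated 10 December 2012. The RPKM values are, per the file headers, reads per kilobase of exon per 1000000 normalization reads, computed by the authors for each library. The read counts deposited beside them are, per the file headers, whole numbers of reads per gene model with no normalization. Whether the counting used the strand of the reads is not given in the sources used here, so reads from a gene and its antisense partner could not be told apart.

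Each table held 21846 entries. Repeated entries of 1 locus, 74 in number, were dropped, which left 21772, of which 17956 had a coding RefSeq accession and 3816 did not. The authors' counting merged overlapping gene models into single entries in 1909 cases, and the insulin gene INS was counted together with IGF2, GHRL with GHRLOS, and HAS2 and LEF1 each with an antisense RNA. A further 357 entries shared a symbol with another locus and were kept apart under numbered names. Near-identical genes, such as the pepsinogen genes PGA3, PGA4 and PGA5 or the MBD3L genes, could share reads, and their separate values are uncertain. The gene length implied by reads and RPKM was compared between libraries over 12752 entries with 20 or more reads in every library. It differed by under 1% in 68.1% of them and by over 1.2 times in 3.4%, the merged INS and IGF2 entry included, so the fold of a single gene is given by reads, and log2 ratios are those of RPKM + 1 unless named as read ratios. For 3 entries a library had reads but an RPKM of 0. The reference annotation at hand was of another genome build, so no coordinates are given and symbols are those of the deposited tables.

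Per the file headers, the control, SCG, 4F and 4F+SCG libraries had 92432034, 64635086, 26091354 and 24134918 mapped reads, of which 59704902, 40502435, 17331757 and 15426645 served as normalization reads. The read counts summed over entries came to 63927485, 44523399, 18964900 and 17580678. In a gene of 2 kb, 3 reads corresponded to an RPKM of 0.0251, 0.0370, 0.0866 and 0.0972 in the same order, so low values were read less precisely in the libraries with 4F. The fold of a named gene is the ratio of its reads per normalization read, with an exact (Clopper-Pearson) 95% interval conditional on the sum of both read counts. With 0 reads in a library, a floor of 3 reads in that library was used and the fold is given as a lower bound. Intervals and floors cover counting error only, since reads were not collapsed to molecules and cultures were not repeated.

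With 1 library per treatment, no p-value was computed for a comparison of a pair of libraries, and differences between them have no replicate check. Genes were counted as 2-fold apart when log2(RPKM + 1) differed by at least 1 and the pair of libraries held at least 20 reads together. The pseudocount of 1 RPKM shrinks the ratios of low genes. The comparisons were SCG against control, 4F+SCG against 4F, 4F against control and 4F+SCG against SCG. The SCG comparisons share no library with each other, and neither do the 4F comparisons, so their ratios were correlated over 12858 genes with a mean RPKM of at least 1, and genes that met the size rule in both were counted beside the number that independent lists would share.

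The 1 test across libraries used the read counts of all 4 in an additive model (4F and SCG as separate terms) with edgeR's quasi-likelihood test, filterByExpr, TMM normalization and Benjamini-Hochberg adjustment at 0.05. This model had 1 residual degree of freedom, treats any difference of an effect between backgrounds as spread, and gave a biological coefficient of variation of 15.1%. The words rose and fell are used only for genes past this test. It asks for a mean effect over both backgrounds, while the folds given beside these words are those of a pair of libraries and were not tested. Tested on simulated data drawn from the libraries' own means with 200 changed genes, the SCG term recovered 74.5% of 2-fold changes among 15512 genes with 8 false calls, and 100% of 4-fold and of 8-fold changes among 15491 and 15454 genes with 7 and 12 false calls. The 4F term recovered 52.5% of 2-fold changes among 15525 genes with 1 false call, and 100% of 4-fold and 8-fold changes among 15518 and 15486 genes with 10 and 3 false calls. These simulated data gave every gene the same spread, which need not hold for the 4 libraries, so the recovered shares may be too high for them. The changed genes were drawn only from those above a minimum of expected reads, so recovery among genes with few reads was not measured. The simulated intervals covered the true ratio in 96.5% of cases.

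The size rule, the tests, the named genes, the alternatives and 32 gene lists were fixed before the data were examined. Named genes were the 10 highest and 10 lowest protein-coding genes that met the size rule in SCG against control, 4F+SCG against 4F and 4F against control, up to 10 coding genes per direction that met it in the same direction in both SCG comparisons, 17 pancreatic and signalling genes whatever their values, and up to 4 members of each list described with the largest log2 ratios in that comparison. Some of these genes are not reported here. The lists covered pancreatic progenitor genes, endocrine transcription factors, islet hormones, endocrine secretory machinery, beta cell function, acinar, ductal, liver, intestine and stomach, pluripotency, definitive endoderm, mesenchyme, neural, endothelial, and blood and mast cell genes. They also covered the BMP pathway and its targets, TGF-beta targets, Notch, Wnt targets, cAMP and CREB targets, glucocorticoid targets, cell cycle, the unfolded protein response, p53 targets, hypoxia and glycolysis, cholesterol synthesis, the interferon response, heat shock, mitochondrially encoded genes, replication-dependent histones, cytosolic ribosomal proteins and cromoglicate-associated genes. Members with a mean RPKM of at least 0.5 counted as measured. Each list's median log2 ratio was set among the medians of 10000 random lists of equal size matched on mean expression in 20 bins, and its percentile among them describes these libraries and is not a p-value. In a test on simulated data a shifted list was placed at percentile 100. Lists with fewer than 4 measured members got no percentile. Lists of genes of the cleavage-stage embryo, primitive streak and presomitic mesoderm, HOX genes and gastric chief cell genes were chosen after the data were seen and appear only in the closing observations.

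Alternatives fixed in advance were pseudocounts of 0.1 and 5 RPKM, rescaling by TMM or by the median gene, a minimum mean RPKM, coding genes only, a 1.5-fold threshold, TMM-scaled read counts (CPM), no filter in the additive test, and DESeq2 or limma in place of edgeR. Reads thinned to the depth of the shallowest library, and scaling without the ribosomal RNA precursor, were added after the data were seen. No entry for a mitochondrially encoded gene was found in the tables, so that list has no result. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.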

Results

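Gene expression was measured by RNA sequencing in 4 cultures of cells derived from human 201B7 iPSCs, each taken on day 8 of the last step of a pancreatic differentiation protocol. The labels describe the cells as derived from PDX1-positive pancreatic progenitors, but the PDX1 transcript was scarce, with an RPKM of 0.111 in control and 0.154 in SCG, where the pluripotency gene POU5F1 had 85.2 and 301. The groups were control, SCG, 4F and 4F+SCG, with 1 library each. The libraries differed in depth, with 59704902 normalization reads for control, 40502435 for SCG, 17331757 for 4F and 15426645 for 4F+SCG. Genes with an RPKM of at least 1 numbered 12691, 12675, 12459 and 12382 in the same order. The ribosomal RNA precursor took 3.98% of gene reads in control, 6.52% in SCG, 6.46% in 4F and 10.1% in 4F+SCG. No treatment was repeated, so differences between a pair of libraries have no replicate check.

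The comparison of 4F with control, 1 library each, serves as the reference for SCG. The hormone genes SST and GCG rose with 4F. The somatostatin gene SST had an RPKM of 0.371 in control and 403 in 4F, a 1086-fold difference by reads (95% interval 647 to 1989), and the glucagon gene GCG went from 0.142 to 279, or 1963-fold (1096 to 3934). CHGA, the secretory granule protein chromogranin A, was 371-fold higher (296 to 472). The entry that merges INS with IGF2 went from an RPKM of 8.80 to 375, but by reads it was 15-fold higher (14.3 to 15.7). The gene length implied by its reads and RPKM differed between the libraries, and the reason was not tested. Its reads could not be divided between insulin and IGF2. The deepest falls included MSGN1, a factor of the presomitic mesoderm, 345-fold lower (135 to 1267) from an RPKM of 137, and the apelin receptor gene APLNR, 486-fold lower (329 to 751) from 181.

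In 4F against control, 2734 genes were 2-fold apart, 1264 higher and 1470 lower, of 15783 with enough reads. Besides SST, GCG, CHGA and the INS entry, the highest coding genes included CGA, the alpha subunit of glycoprotein hormones (533-fold), CLCA1 (1072-fold), the corticotropin-releasing hormone gene CRH (124-fold), S100A7 (61.9-fold) and CRYBA2 (2811-fold, 503 to 111160), which had 1 read in control. The other lowest coding genes were TAC1, which encodes substance P (1009-fold lower), CDX4 (1059-fold lower, 190 to 41839, with 1 read in 4F), FGF17 (425-fold), SP5 (354-fold), the prodynorphin gene PDYN (283-fold), CITED1 (137-fold), WNT5B (82.5-fold) and the entry of HOXB5 and HOXB6 (63.5-fold). All of these passed the additive edgeR test with adjusted p-values between 6.81e-05 for SST and 0.00367 for the HOXB entry.

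**Figure D1:**
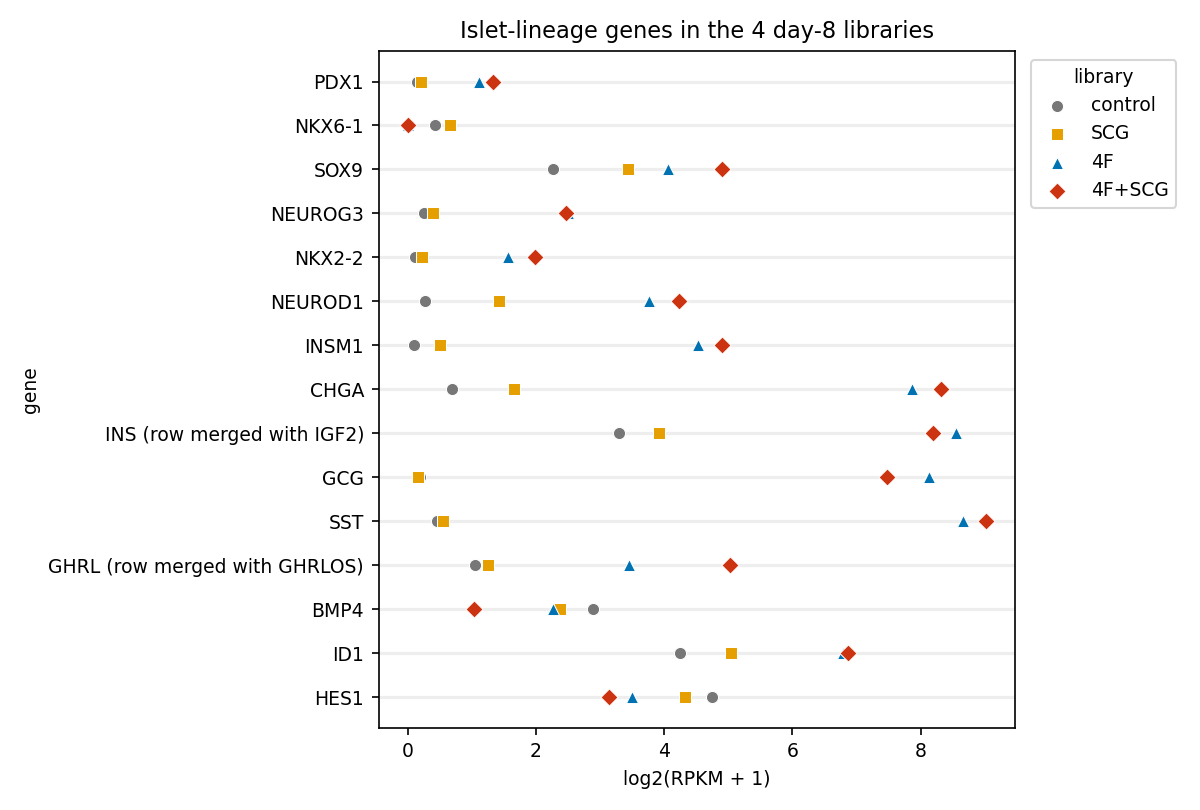
Level of islet-lineage and signalling genes in the 4 libraries, as log2(RPKM + 1) on the horizontal axis, with 1 point per library and no error bars because each group had 1 library. SST lay at an RPKM of 0.371 in control and 403 in 4F, and PDX1 stayed below an RPKM of 2 in each library, at most 1.51 in 4F+SCG.

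Endocrine regulators rose as well. Of all 15492 tested genes 3747 rose and 4000 fell with 4F, which is the background for the list counts that follow. NEUROG3, the factor that starts endocrine commitment, was 23.4-fold higher in 4F than in control (13.6 to 43.4, RPKM 0.200 and 4.69), NEUROD1 59.1-fold, INSM1 311-fold and NKX2-2 24.5-fold. The adjusted p-values of their mean 4F effect over both backgrounds were 0.00127, 0.00341, 7.19e-04 and 0.00118 (edgeR). Of 19 measured endocrine transcription factors 15 rose and 2 fell (16 and 2 adjusted over the list alone), with ISL1 36.2-fold higher. All 6 measured entries of the islet hormone list rose, also when adjusted over the list alone, but these include the merged INS and IGF2 entry, which does not show a rise of insulin by itself, and TTR, a carrier protein gene also in the liver list. PYY was 24.3-fold higher. The ghrelin entry GHRL rose, 4.21-fold by reads. PPY had 6 reads in control and 4 in 4F, and its difference was not detectable at this depth. In the endocrine secretory machinery 19 of 32 genes rose and 2 fell, the same numbers as adjusted over the list alone, and SCGN and SYT4 were 29.3-fold and 45.8-fold higher. Of 20 beta cell function genes 16 rose and 3 fell (16 and 4 adjusted over the list alone). ERO1LB, a protein-folding oxidase, was 22.9-fold higher, while the glutamate decarboxylase gene GAD1 fell from an RPKM of 37.8 to 1.47 and NPTX2 from 16.4 to 0.340.

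Progenitor genes were divided. PDX1 rose with 4F, 10.5-fold (6.00 to 19.4) from an RPKM of 0.111 to 1.17. NKX6-1 had 23 reads in control and 0 in 4F, at least 2.23-fold lower, and its mean 4F effect over both backgrounds passed the test with an adjusted p of 0.0213 (edgeR). PTF1A, which marks early multipotent and acinar cells, had 1 read in control and 0 in 4F, too few to compare. SOX9 rose 4.10-fold. Of 11 measured pancreatic progenitor genes 5 rose and 2 fell, with the same numbers adjusted over the list alone, and GP2 stood out with an RPKM of 0.0138 in control and 25.8 in 4F. Of 7 acinar genes 2 rose and 3 fell (the same over the list alone). The carboxypeptidase gene CPB1 was 893-fold higher (305 to 4341; 3 reads in control), whereas CPA1 fell, to a ratio of 0.0461. Among 14 ductal genes 9 rose and 4 fell (the same over the list alone), CLDN4 by 10.2-fold and KRT19 by 3.75-fold upwards.

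Genes of other endodermal organs also moved. Of 21 liver genes 16 rose and 1 fell (the same over the list alone), with the fetal cytochrome entry CYP3A7 109-fold, APOC3 24.8-fold and APOA1 6.99-fold higher. The gene that fell was FGB, with an RPKM of 1030 in control and 415 in 4F. AFP had 1608 and 613 but did not pass the test. Some liver genes were also abundant without 4F, such as APOA1 with an RPKM of 309 in control, while CYP3A7 and APOC3 had 0.394 and 2.51 there. Of 11 intestine and stomach genes 6 rose and 4 fell (the same over the list alone), with FABP1 64.4-fold and LYZ 212-fold higher and the intestinal factors CDX1 and CDX2 lower, at ratios of 0.00919 and 0.0871. Of 10 definitive endoderm genes 5 rose and 4 fell (the same over the list alone), KIT 5.84-fold and SOX17 3.61-fold upwards and CXCR4 and MIXL1 downwards, from RPKM 184 to 6.98 and from 28.4 to 0.413.

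Pluripotency genes fell with 4F in 10 of 12 cases and 1 rose (11 and 1 adjusted over the list alone). POU5F1, the core pluripotency factor, had an RPKM of 85.2 in control and 1.2 in 4F, and SALL4 and DPPA4 fell to ratios of 0.158 and 0.174. Of 26 cell cycle genes 22 fell and 2 rose (the same over the list alone), with the mitotic activator CDC20 at a ratio of 0.323 and MCM2 at 0.390. Replication-dependent histone genes fell in 17 of 19 cases (the same over the list alone), such as HIST1H1D at 0.380, and cytosolic ribosomal protein genes in 26 of 33 (29 over the list alone), such as RPS2 at 0.514. Neural genes included 5 that rose and 8 that fell of 15 (the same over the list alone). NES fell to a ratio of 0.172. Of 22 mesenchyme genes 6 rose and 10 fell (6 and 11 over the list alone), with COL1A2 and THY1 at ratios of 0.168 and 0.189. Of 6 endothelial genes 3 rose and 2 fell (the same over the list alone), and the VEGF receptor gene KDR was 37.2-fold higher. Both measured blood and mast cell genes fell, also over the list alone, CORO1A to a ratio of 0.210 and CD68 to 0.471. Among the cromoglicate-associated genes 1 of 3 rose, also over the list alone, and this was S100P, 10.3-fold (4.72 to 25.0).

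Signalling lists moved in several directions with 4F. Of 15 Wnt targets 11 fell and 3 rose (the same over the list alone), with DKK1 going from an RPKM of 121 to 1.69 and CCND1 from 49.6 to 1.79, and NOTUM from 14.2 to 0.0260. Of 17 Notch genes 12 fell and 2 rose (the same over the list alone). DLL3 and LFNG fell to ratios of 0.0177 and 0.0358 and HES1 to 0.400, while HEY1 rose 25.9-fold. Of 22 cAMP and CREB targets 13 rose and 1 fell (the same over the list alone), PDE4D 14.2-fold and AREG 11.6-fold upwards, with the AREG locus counted in more than 1 copy. Of 23 glucocorticoid targets 9 rose and 5 fell (10 and 6 over the list alone), with PDK4 12.4-fold higher and the metallothionein genes MT2A and MT1X at ratios of 0.182 and 0.174. Of 24 BMP pathway genes 9 rose and 6 fell (9 and 7 over the list alone). The BMP-responsive ID1, ID2 and ID4 rose 6.08-fold, 6.38-fold and 8.18-fold, while BMP4 itself fell to a ratio of 0.578 (0.471 to 0.705) and MSX1 to 0.0612. Of 22 TGF-beta targets 12 fell and 5 rose (13 and 6 over the list alone), with TGFBI 6.09-fold higher and COL1A1 at a ratio of 0.256.

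Stress and metabolic lists held genes that rose and genes that fell. Of 18 unfolded protein response genes 6 rose and 7 fell, of 16 p53 targets 4 rose and 4 fell, of 23 hypoxia and glycolysis genes 4 rose and 10 fell, of 19 cholesterol synthesis genes 1 rose and 6 fell, of 8 interferon response genes 1 rose and 2 fell, and of 11 heat shock genes 2 rose and 4 fell, in each case with the same numbers adjusted over the list alone. ENO2 fell to a ratio of 0.188, FDXR to 0.414, ISG15 to 0.240 and CHAC1 to 0.349, and HSP90AB1 to 0.488. In total 7747 of 15492 tested genes passed the additive test for 4F, 3747 up and 4000 down. Several list medians in 4F against control lay among those of random lists. The percentile was 93.8 for pancreatic progenitor genes and for the BMP pathway, and 91.9 for glucocorticoid targets. It was 89.6 for definitive endoderm, 88.5 for heat shock, 75.2 for the unfolded protein response and 67.6 for p53 targets. For the interferon response it was 32.2, for endothelial genes 29.9, for mesenchyme 5.44 and for TGF-beta targets 4.12.

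**Figure D2:**
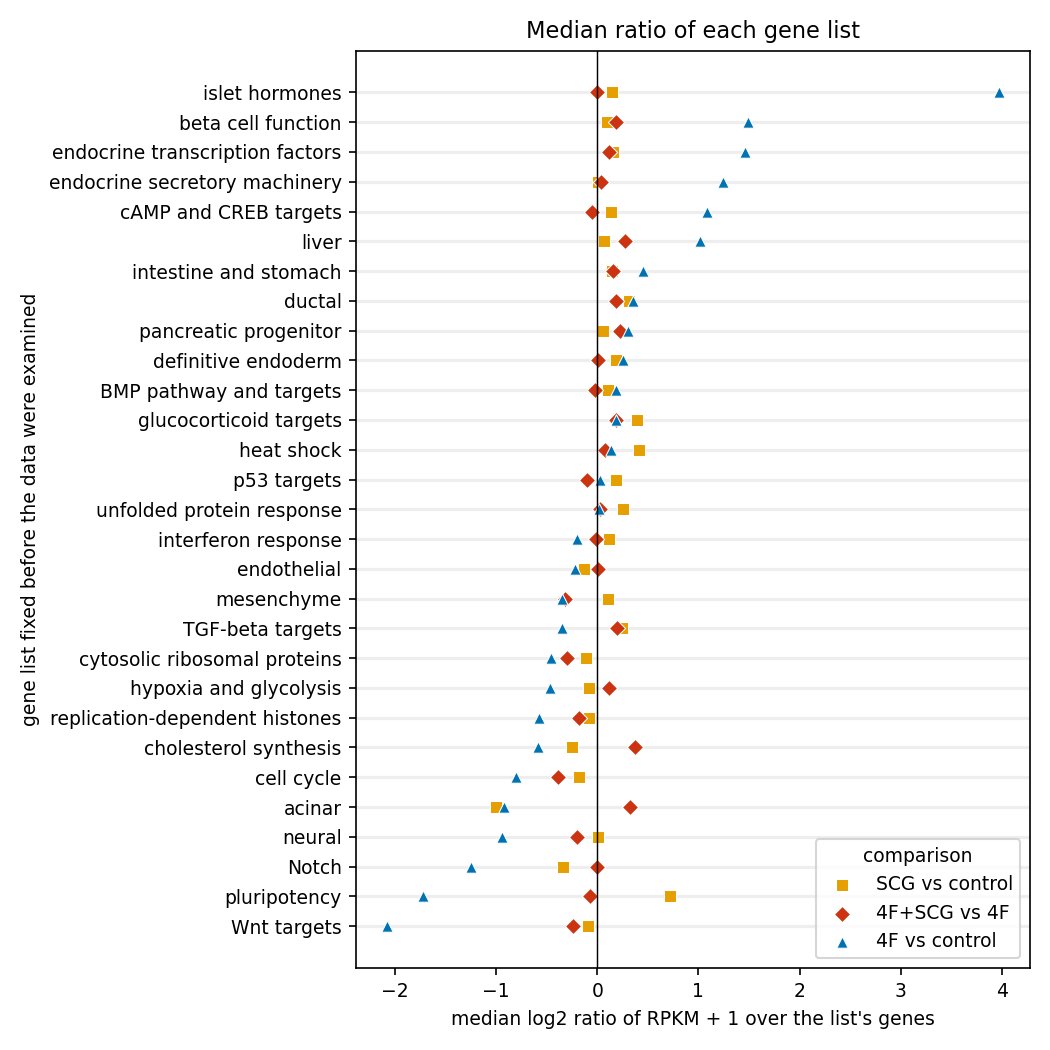
Median log2 ratio of RPKM + 1 over the measured genes of each list, with 1 symbol for each of 3 comparisons of a pair of libraries and no error bars because each group had 1 library. With 4F against control the medians ran from 3.97 for islet hormones to -2.08 for Wnt targets, and with SCG against control from 0.72 for pluripotency to -0.999 for acinar genes.

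The same factors were compared with SCG present, in 4F+SCG against SCG. There SST was 1109-fold higher (634 to 2147), GCG 1552-fold (712 to 4231), CHGA 146-fold (126 to 171), NEUROG3 14.4-fold (8.42 to 26.4) and PDX1 9.85-fold (5.6 to 18.3). NEUROD1 was 10.5-fold, INSM1 67.3-fold, NKX2-2 17.8-fold, SOX9 2.96-fold, the INS entry 6.85-fold, GHRL 7.71-fold and ID1 3.60-fold higher by reads. BMP4 and HES1 were lower, at ratios of 0.232 and 0.408, and NKX6-1, with 26 reads in SCG and 0 in 4F+SCG, was at least 3.30-fold lower. PTF1A had 1 read and 0, and PPY 2 reads and 0, too few to compare. POU5F1 was 216-fold lower (148 to 331). Of 15319 genes 2639 were 2-fold apart, 1131 higher and 1508 lower. The list medians were 4.03 for islet hormones, 1.56 for beta cell function, 1.34 for endocrine secretory machinery, 1.10 for endocrine transcription factors, -2.53 for pluripotency and -2.96 for Wnt targets. Across 12858 genes the 4F ratios without and with SCG had a Pearson correlation of 0.892 and a Spearman correlation of 0.880, where genes are not independent replicates. In both comparisons 921 genes were higher and 996 lower, where independent lists would share 93.3 and 140, and 4 genes were 2-fold apart in opposite directions.

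The first comparison named in the series design asks what SCG did in the absence of 4F. In the SCG library the endocrine factor NEUROD1 was 7.99-fold higher than in control (5.63 to 11.6; RPKM 0.212 and 1.69), INSM1 6.02-fold (3.16 to 12.4) and CHGA 3.47-fold (2.64 to 4.60), all at low levels. SOX9 was 2.56-fold higher (2.35 to 2.78). Of 12 pluripotency genes 4 were 2-fold higher and 8 were not 2-fold apart, and the former included POU5F1, higher by 3.46-fold (3.36 to 3.56; RPKM 85.2 and 301) and NANOG by 3.83-fold (3.38 to 4.34). The 3 pepsinogen genes PGA3, PGA4 and PGA5, which encode gastric protease precursors, were 11.6-fold, 11.8-fold and 11.5-fold higher, and REG3A, an antimicrobial lectin gene of gut and pancreas, was 429-fold lower (147 to 2084; 1899 and 3 reads).

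In all, 490 of 16019 genes were 2-fold apart between SCG and control, 270 higher and 220 lower. The highest coding genes were CCNA1, the germline cyclin A1 (16.8-fold, 14.6 to 19.4, RPKM 2.08 and 35.3), the placental-type phosphatase ALPPL2 (15-fold, 12.8 to 17.5), the germ cell and oocyte gene DPPA3 (16.1-fold, 12.2 to 21.6), the near-identical MBD3L2, MBD3L3, MBD3L4 and MBD3L5 (14.9-fold to 18.3-fold) and the pepsinogen genes. Besides REG3A, the lowest were PRL, the prolactin gene (46.5-fold lower, 23.4 to 108), SEZ6L (27.0-fold), the T cell kinase gene ZAP70 (26.8-fold), PDYN (23.4-fold), the sterol exporter gene ABCG1 (13.8-fold), the HOXB5 and HOXB6 entry (13.7-fold), FGF1 (12.4-fold), TAC1 (10.3-fold) and VWA2 (8.39-fold).

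Of the other pancreatic genes followed throughout, PDX1 had a ratio of 1.39 (0.656 to 2.92), NKX6-1 of 1.67 (0.914 to 3.06), NEUROG3 of 1.57 (0.728 to 3.41), NKX2-2 of 2.06 (0.853 to 5.19), GCG of 0.804 (0.244 to 2.37) and SST of 1.26 (0.534 to 2.94), and none of these differences was detectable at this depth. The same held for GHRL at 1.37 (0.996 to 1.88). PTF1A had 1 read in each library and PPY had 6 and 2 reads, too few to compare. The INS entry was 1.61-fold higher (1.52 to 1.71). BMP4 had a ratio of 0.653 (0.569 to 0.748) and HES1, a Notch target, of 0.739 (0.688 to 0.794), while ID1 was 1.78-fold higher (1.64 to 1.93).

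The highest list medians of SCG against control were those of pluripotency (0.72, percentile 100), heat shock (0.42, percentile 100), glucocorticoid targets (0.40, percentile 100), ductal genes (0.31, percentile 99.96), the unfolded protein response (0.25, percentile 99.99) and TGF-beta targets (0.25, percentile 99.98). TDGF1 was 3.60-fold and ZFP42 2.56-fold higher, the chaperone genes HSPA1A and HSPA1B 2.03-fold and 2.13-fold, the metallothionein gene MT1X 5.25-fold, CLDN4 2.85-fold and KRT19 2.01-fold. The amino acid stress genes ASNS, CHAC1 and TRIB3 were 2.99-fold, 3.13-fold and 2.74-fold higher, and NODAL and TGFBI 7.39-fold and 3.00-fold. Within the same lists GLUL was lower, at a ratio of 0.431. The lowest medians were those of acinar genes (-0.999, percentile 0), Notch genes (-0.34, percentile 0.04), cholesterol synthesis (-0.25, percentile 0.23) and cell cycle (-0.18, percentile 1.28). CPA1 and the trypsin inhibitor gene SPINK1 had ratios of 0.128 and 0.347, and LFNG, HEYL and DLL3 of 0.327, 0.208 and 0.433, while HEY1 was 3.12-fold higher. HMGCS1 had a ratio of 0.640 and E2F1 of 0.610.

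The other list medians with SCG alone lay between -0.13 and 0.18. They were 0.15 for endocrine transcription factors (percentile 98.2), 0.14 for islet hormones (91.5), 0.10 for beta cell function (96.0), 0.01 for endocrine secretory machinery (78.3), 0.05 for pancreatic progenitor genes (81.9), 0.06 for liver (93.1), 0.14 for intestine and stomach (95.1), 0.18 for definitive endoderm (98.0) and 0.10 for mesenchyme (97.9). Members still differed within these lists. The apolipoprotein gene APOB was 2.90-fold higher and ALB had a ratio of 0.363, EOMES was 8.32-fold higher and CXCR4 had a ratio of 0.306, COL3A1 and FN1 were 2.29-fold and 2.11-fold higher, and the granule protein genes SCG3 and SCG5 had ratios of 2.26 and 0.311. Among Wnt targets, with a median of -0.09 (percentile 28.0), the inhibitor gene DKK4 was 9.31-fold higher and NOTUM and LEF1 had ratios of 0.130 and 0.407. The medians were 0.11 for the BMP pathway (98.0), 0.13 for cAMP and CREB targets (98.9), 0.18 for p53 targets (99.5), 0.12 for the interferon response (89.7), 0.01 for neural (70.6), -0.13 for endothelial (22.8), -0.09 for hypoxia and glycolysis (28.1), -0.08 for histones (30.7) and -0.11 for ribosomal proteins (7.28).

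The second comparison of the series design asks what SCG added to 4F. CHGA was 1.37-fold higher in 4F+SCG than in 4F (1.33 to 1.41; RPKM 231 and 317), NEUROD1 1.42-fold (1.28 to 1.58), INSM1 1.30-fold (1.2 to 1.42), SST 1.29-fold (1.24 to 1.34) and the ghrelin entry 2.51-fold (1.98 to 3.19). GCG and the INS entry were lower, at ratios of 0.636 (0.610 to 0.663) and 0.738 (0.715 to 0.761). NEUROG3 had a ratio of 0.969 (0.720 to 1.30), with no detectable difference at this depth. SOX9 was 1.85-fold higher (1.71 to 1.99), and BMP4 was lower, at a ratio of 0.262 (0.165 to 0.400; 116 and 27 reads).

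Between 4F+SCG and 4F 114 of 14149 genes were 2-fold apart, 46 higher and 68 lower, so 40.4% were higher. With RPKM rescaled by TMM or by the median gene the division was 62 higher and 59 lower, 51.2% higher. The highest coding genes were the stress-response gene NUPR1 (8.21-fold, 4.58 to 16.0), the lactase entry LCT (7.99-fold), ZG16 (4.99-fold), the oxidase gene DUOX2 (3.90-fold) and the entry of its maturation factors DUOXA1 and DUOXA2 (4.02-fold), AGPAT9 (3.84-fold), PGA4 (3.44-fold), PGA3 (3.31-fold) and GHRL. The entry that merges CTNS, EMC6, P2RX5 and TAX1BP3 met the rule by RPKM, 33.0 and 101, but was 1.11-fold higher by reads (1.04 to 1.17). The lowest were GNG11 (9.61-fold lower, 3.87 to 30.8), the matrix genes POSTN and DCN (7.83-fold and 3.98-fold), TMSB15A (6.19-fold), the chemokine gene CXCL14 (5.91-fold), CST1 and CST4, similar cystatin genes (4.79-fold and 3.69-fold), PLAT (4.64-fold), the glutamate receptor gene GRIA4 (4.26-fold) and the neurotensin gene NTS (3.38-fold). PDX1 had a ratio of 1.30 (0.879 to 1.92), ID1 of 1.05 (0.986 to 1.12), NKX2-2 of 1.5 (1.09 to 2.07) and HES1 of 0.755 (0.620 to 0.917). NKX6-1 and PTF1A had 0 reads in both libraries, and PPY had 4 reads in 4F and 0 in 4F+SCG.

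The list medians farthest above random lists in 4F+SCG against 4F were cholesterol synthesis (0.37, percentile 100), liver (0.28, percentile 100), acinar (0.33, percentile 99.75), pancreatic progenitor (0.22, percentile 99.6), TGF-beta targets (0.20, percentile 99.99), beta cell function (0.19, percentile 99.95), glucocorticoid targets (0.19, percentile 99.95) and ductal genes (0.18, percentile 99.76). MSMO1 was 1.68-fold higher, AFP 1.84-fold, TDO2 2.27-fold, RBP4 1.97-fold, CPB1 2.28-fold, FOXA2 1.60-fold, COL4A1 1.81-fold, ENTPD3 2.64-fold and S100A6 2.17-fold, whereas the ductal gene SPP1 had a ratio of 0.297. The medians lowest against random lists were cell cycle (-0.39, percentile 0), cytosolic ribosomal proteins (-0.29, percentile 0), mesenchyme (-0.32, percentile 0), Wnt targets (-0.24, percentile 0.775) and neural genes (-0.20, percentile 2.13). CENPF and TOP2A had ratios of 0.561 and 0.638, RPS6 and RPL5 of 0.587 and 0.612, TBX18 and COL1A2 of 0.334 and 0.540, DKK1 and LEF1 of 0.0424 (0.00500 to 0.161) and 0.526, and DCX of 0.399.

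The remaining medians in this pair were 0.12 for endocrine transcription factors (percentile 98.5), 0.04 for endocrine secretory machinery (93.1), 0.16 for intestine and stomach (98.5), 0.11 for hypoxia and glycolysis (99.3) and 0.07 for heat shock (90.7). ALDOC, a glycolytic enzyme gene, was 2.5-fold higher, CLDN18, a tight junction gene of stomach, 2.22-fold, and SNAP25 had a ratio of 0.351. The median was -0.07 for pluripotency (36.2), -0.10 for p53 targets (20.0), -0.18 for histones (11.6), 0.03 for the unfolded protein response (86.2), 0.01 for endothelial genes (61.9), and 0.00 for definitive endoderm (66.8) and Notch (69.4). For islet hormones (0.00, percentile 68.7), the BMP pathway (-0.02, percentile 56.6), cAMP and CREB targets (-0.05, percentile 43.9) and the interferon response (-0.01, percentile 57.6) the median lay so near 0 that its sign turned to positive with TMM rescaling. No median is given for the 2 measured blood and mast cell genes or the 3 cromoglicate-associated genes, where CD68 had a ratio of 1.85 (1.24 to 2.78) and the S100A13 entry of 0.960 (0.91 to 1.0) with SCG on top of 4F, and 1.5 (1.28 to 1.76) and 0.829 (0.803 to 0.855) with SCG alone.

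Genes 2-fold apart with SCG both without and with 4F were counted next, since these comparisons share no library. The pepsinogen genes were higher in both, PGA4 by 11.8-fold and 3.44-fold, PGA3 by 11.6-fold and 3.31-fold and PGA5 by 11.5-fold and 3.14-fold, although their near-identical sequences could share reads. The myosin gene MYH7 was 19.4-fold and 4.50-fold higher, ATP6V0D2 4.83-fold and 5.92-fold, PLA1A 4.24-fold and 3.71-fold, the inhibin gene INHA 3.73-fold and 2.84-fold, PTPRR 3.67-fold and 3.15-fold, C1QTNF6 2.67-fold and 2.5-fold, and the potassium channel gene KCNK12 2.57-fold and 2.49-fold. Lower in both were GNG11 (4.34-fold and 9.61-fold), the hyaluronan synthase entry HAS2 (3.54-fold and 3.41-fold), the chemokine receptor gene CXCR4 (3.26-fold and 2.52-fold), FGF10 (3.10-fold and 8.23-fold), BEX5 (2.97-fold and 3.81-fold), TCEAL7 (2.76-fold and 2.65-fold) and the merged LEF1 entry (2.46-fold and 1.90-fold). The LEF1 entry met the size rule by RPKM in both comparisons, but by reads it was under 2-fold lower with 4F.

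In both SCG comparisons 12 genes were higher and 7 lower, where independent lists would share 0.595 and 0.654, and 2 genes were 2-fold apart in opposite directions, where 1.33 were expected. The higher ones included the noncoding SNORA53, 2.59-fold and 3.28-fold. They also included the near-identical PGA3, PGA4 and PGA5, which can share reads. Among the lower ones was the LEF1 entry, under 2-fold lower by reads with 4F. The expected numbers treat all of these as separate genes. Of 237 expressed genes 2-fold higher with SCG alone, 70.5% were higher with SCG on top of 4F, with a median log2 ratio of 0.19, and of 191 that were 2-fold lower with SCG alone 61.3% were lower, with a median of -0.08. Over all 12858 expressed genes 43.5% were higher and 56.3% lower in that pair, with a median of -0.04, so the genes lower with SCG alone lay close to this background. Read the other way, 86.0% of 43 genes higher with SCG on top of 4F were higher with SCG alone, and 67.7% of 65 lower ones were lower, against 43.5% and 56.5% of all expressed genes. Across 12858 genes the SCG ratios without and with 4F had a Pearson correlation of 0.304 and a Spearman correlation of 0.396, with genes not being independent replicates.

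**Figure D3:**
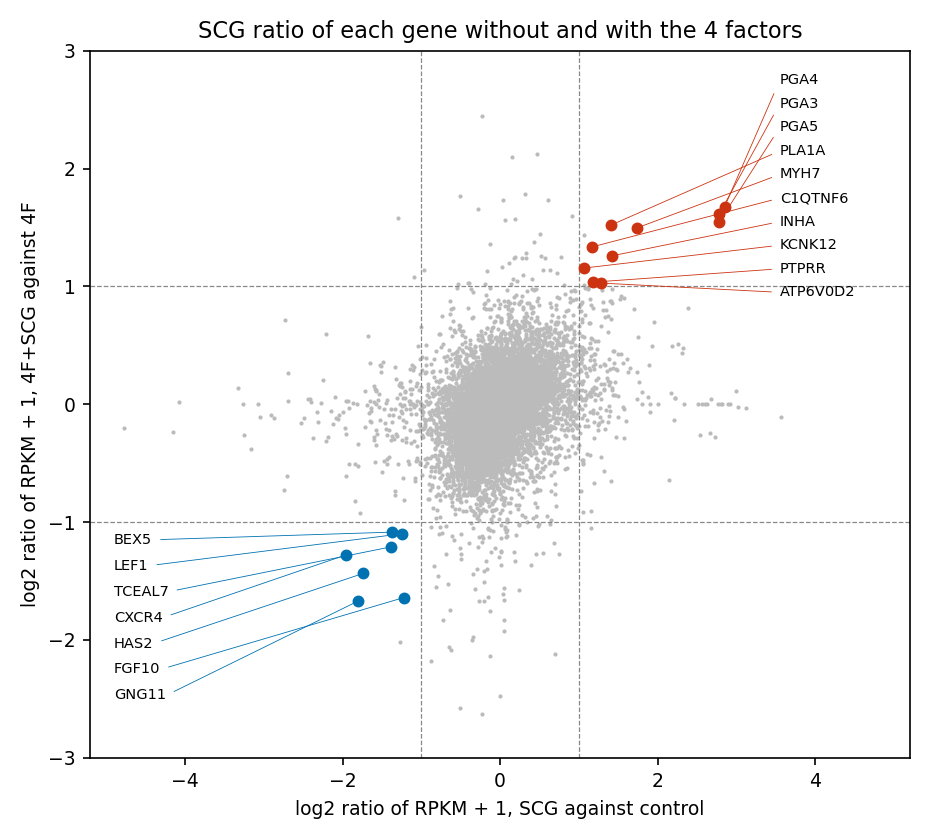
Log2 ratio of RPKM + 1 with SCG for each gene, SCG against control on the horizontal axis and 4F+SCG against 4F on the vertical axis, with 1 grey point per gene of mean RPKM at least 1 and dashed lines at 2-fold. Coloured points are named coding genes 2-fold apart in the same direction in both comparisons, such as PGA4 (2.85 and 1.68) and GNG11 (-1.81 and -1.67).

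The additive edgeR test for a mean SCG effect over both backgrounds passed 0 of 15492 genes, with a smallest adjusted p of 0.125. At an unadjusted p under 0.05 it held 2522 genes, DESeq2 passed 255 (193 up and 62 down) and limma 0. Adjusted over the list alone, the SCG term passed 7 liver genes upwards, 5 ductal genes upwards and 1 downwards, 5 TGF-beta targets upwards, 4 glucocorticoid targets upwards, 4 heat shock genes upwards, and 4 pluripotency genes upwards and 1 downwards, against 0 in each list over all genes. Upward and downward calls over the list alone numbered 3 and 1 for pancreatic progenitor genes, islet hormones, endocrine secretory machinery and definitive endoderm, 3 and 3 for Wnt targets, 2 and 1 for intestine and stomach, and 1 and 2 for acinar genes. They numbered 2 and 0 for beta cell function and for hypoxia and glycolysis, 1 and 0 for endocrine transcription factors, p53 targets and cholesterol synthesis, 0 and 1 for endothelial and Notch genes, and 0 in both directions for the other lists. Each list was adjusted by itself, with no correction across the lists. With 2522 of all 15492 genes under the unadjusted limit, these calls do not by themselves show that a list responded to SCG. On simulated data in which an effect was alike in both backgrounds, this term recovered 74.5% of 2-fold changes. Those data gave every gene the same spread and left genes with few reads unchanged, so this share need not hold for the 4 libraries. The count of 0 genes therefore does not exclude SCG effects of 2-fold or more.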

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

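Of the tests in this part, the test on reads shared between near-identical gene copies was set before its values were seen, the other tests were chosen after the results were seen, and the test of BMP targets was also divided by background and widened from 5 to 10 genes, and that of liver genes widened from 3 to 21 genes, after their values were seen. The ratios with SCG were examined for genes and lists that went one way without 4F and the other way with it, and for each of these the difference was not tested, since each group had 1 library. The acinar genes had a median log2 ratio of -0.999 without 4F (percentile 0) and 0.33 with it (percentile 99.75), a difference of 1.33 that was not tested. The cholesterol synthesis genes had medians of -0.25 (percentile 0.23) and 0.37 (percentile 100), and the difference of 0.62 was not tested. The mesenchyme genes had medians of 0.10 (percentile 97.9) and -0.32 (percentile 0), and this difference of -0.42 was not tested either. VIT had log2 ratios of 1.16 without 4F and -1.05 with it, 3.45 and 0.428 by reads, and the difference of -2.21 was not tested. For the entry that merges CTNS, EMC6, P2RX5 and TAX1BP3 the log2 RPKM ratios were -1.29 and 1.58, a difference of 2.87 that was not tested, but the ratios by reads were 1.14 and 1.11. The difference therefore lay in the gene length implied by reads and RPKM in each library, and why that length differed was not tested.

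Genes of the cleavage-stage embryo that are known targets of the factor DUX4 were higher in the SCG library than in control, for example LEUTX (15.2-fold, 9.09 to 27.2), ZSCAN4 (10.3-fold, 7.07 to 15.4) and KDM4E (16.5-fold, 11.4 to 24.7). Reads shared between near-identical gene copies are argued against as the whole cause, because 10 of 11 single-copy members whose values had not been seen were at least 2-fold higher. A larger share of pluripotent cells was left open. The median log2 read ratio was 3.83 over all 51 members, 14 of them chosen from values already seen. It was 3.48 and 3.73 over the single-copy and multicopy members not yet seen. NANOG, the highest gene of the fixed pluripotency list, stood at 1.94. The genes of that list need not be confined to pluripotent cells, so their ratios can understate a change in the share. A change within a rare group of pluripotent cells stays open too. Whether SCG has this effect in both backgrounds was left open, since 4 of 51 members had 20 reads in the pair with 4F and 0 of these were 2-fold higher there. Among these, SLC34A2 was 9.12-fold higher with SCG alone but lower with SCG on top of 4F, at a ratio of 0.221 (0.108 to 0.415), and the others lay within 2-fold there. With 1 culture per treatment the pattern cannot be tied to SCG itself.

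In control some pluripotency genes and some genes of a primitive streak and presomitic mesoderm list were abundant, such as POU5F1 (RPKM 85.2) and MSGN1 (137), while others of that list, such as EOMES (0.465), were scarce, and in 4F against control 21 of its 24 entries with enough reads were at least 2-fold lower by reads, with a median log2 RPKM ratio of -4.97. That these libraries were undifferentiated iPSC cultures throughout is argued against by the liver list, of which 16 of 21 measured genes lay within 10-fold of the 4F libraries in both backgrounds, and AFP, FGB and APOB together had an RPKM of 2698 in control and 2007 in SCG against 1090 in 4F and 1640 in 4F+SCG. The other 5, CYP3A7, CYP3A4, APOC3, TAT and HP, were over 10-fold lower without 4F in both backgrounds, so an undifferentiated part of the cells stays open. The authors' scaling is argued against, because over 34 genes of both lists the median log2 ratio with 4F stayed between -3.57 and -3.24 under both rescalings and in both backgrounds. A difference in the state or mix of the cultures other than the 4 factors cannot be told apart from their effect, since there was 1 library per treatment.

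BMP4 was lower with SCG in both backgrounds, with ratios of 0.653 and 0.262. Counting noise is argued against, since the upper limits of these ratios were 0.748 and 0.400. Lower BMP signalling stays open without 4F, where the 10 measured BMP target genes of the list went both ways. Their median log2 ratio was 0.43 (interval -0.56 to 1.2), with 7 of 10 above 0. ID1, ID2, ID3 and ID4 were at 0.80, 1.26, 0.30 and 0.62 and BAMBI at 1.2, while MSX1 and ATOH8 were at -0.56 and SMAD6 at -0.005. Lower BMP signalling stays open with 4F too, where the median was 0.012 (interval -0.33 to 0.12) with 5 of 10 above 0. Each interval runs from the 2nd lowest to the 2nd highest of the 10 ratios, so it shows the spread among genes and not between cultures. A lower BMP4 transcript level with SCG may therefore be an effect of the compound or a difference between single cultures, and these cannot be told apart here.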

How the results depend on the processing

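Tests with reads thinned to the shallowest library, and with the ribosomal RNA precursor left out of the scaling, were chosen after the results were seen, and all other alternatives were fixed in advance. No paired analysis was possible because the labels give no replicate numbers that tie libraries across groups. Counts of 2-fold genes for SCG against control, 4F+SCG against 4F, 4F against control and 4F+SCG against SCG were 490, 114, 2734 and 2639 as reported. They became 1217, 430, 4513 and 4273 with a pseudocount of 0.1 RPKM, 162, 27, 1271 and 1247 with 5 RPKM, and 1601, 787, 5693 and 5630 with a 1.5-fold threshold, as the lighter or heavier shrinkage and the lower threshold imply. TMM-scaled CPM gave 733, 190, 3423 and 3336 in the same order. There the 1 was added to CPM and not to RPKM, so the shrinkage differed with gene length, and its share in these counts was not tested. The direction of 4F+SCG against 4F rested on the scaling, with 40.4% of its genes higher as reported, 51.2% (62 higher, 59 lower) with TMM or the median gene, and 51.6% (63 higher, 59 lower) without the ribosomal RNA precursor. Thinning gave 507, 113, 2742 and 2638, so depth had little part in these counts. The correlation of SCG ratios, 0.304 as reported, was 0.249 and 0.349 with pseudocounts of 0.1 and 5, 0.339 for coding genes and 0.386 at a mean RPKM of at least 5, and that of 4F ratios, 0.892, was 0.886, 0.898, 0.902 and 0.920, and the cause was not tested. Shared SCG genes, 19 as reported, numbered 76, 3 and, at a mean RPKM of at least 5, 12, and shared 4F genes, 1917, numbered 3184 and 900 with the same pseudocounts. The additive test for SCG passed 5 genes without a filter and 255 with DESeq2 against 0 with edgeR, and the cause was not tested, while for 4F it passed between 5981 and 7751. The CTNS entry reversed for SCG against control, from -1.29 to 0.22 in CPM, which use no gene length. Among 1755 alternative values for 585 results of named genes this was the only reversal of a 2-fold difference, and those beyond their interval numbered 41 with TMM, 157 with CPM and 195 with a pseudocount of 0.1. Of 456 alternative list medians 0 reversed where the list stood apart from random genes, and those beyond the random spread numbered 0 with TMM, 22 at a mean RPKM of at least 2, and 27 and 40 with pseudocounts of 0.1 and 5.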

Other observations

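The lists described here were chosen after the results were seen, and no explanation for them was tested. HOX genes, which pattern the embryo from head to tail, were lower in the SCG library than in control. Of 23 HOX entries with enough reads 17 were at least 2-fold lower by reads and 0 were 2-fold higher, and the median log2 RPKM ratio of 18 entries was -1.41 (percentile 0). HOXB9 had an RPKM of 47.2 in control and 14.3 in SCG, HOXB3 of 20.9 and 4.63, and HOXD4 of 7.82 and 0.762. In 4F against control 21 of 23 HOX entries were at least 2-fold lower by reads, and with SCG on top of 4F this held for 2 of 12. Overlapping HOX gene models were counted as merged entries in part, so single genes of a cluster could not always be resolved.

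Genes of the primitive streak and presomitic mesoderm did not go one way with SCG alone. The streak genes T and EOMES were 2.30-fold (2.22 to 2.38) and 8.32-fold (6.51 to 10.8) higher in SCG than in control, while TBX6, HES7 and FGF8 of the presomitic mesoderm had ratios of 0.419 (0.393 to 0.447), 0.367 (0.337 to 0.399) and 0.223 (0.199 to 0.249). These members were picked for their size, and others lay within 2-fold, such as MIXL1 at 1.33, WNT3A at 1.38 and WNT8A at 1.25 of the streak and MSGN1 at 0.835 of the presomitic mesoderm. Of 24 entries 3 were 2-fold higher and 8 were 2-fold lower by reads. In the gastric chief cell list the median log2 RPKM ratio with SCG was 1.46 without 4F and 1.28 with 4F over 6 measured entries, but these medians rest on the near-identical PGA3, PGA4 and PGA5, which can share reads and had log2 ratios of 2.78, 2.85 and 2.78 without 4F and 1.61, 1.68 and 1.55 with it. Of the other measured entries, CLDN18 and GIF had 0.14 and 0.10 without 4F and 1.02 and 0.17 with it, and CHIA had 0 reads in control and SCG and was lower with SCG on top of 4F, with 46 and 9 reads and a ratio of 0.220 (0.0946 to 0.455). The other pepsinogen gene, PGC, had 3 reads in control and 11 in SCG, a ratio of 5.41 (1.43 to 30.2), and 5 reads in 4F and 3 in 4F+SCG.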
